A study of Aspergillus flavus with 2 samples.

How the data were processed

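Mycelia of Aspergillus flavus NRRL3357 were grown for 24 h at 30 °C or at 37 °C. Per the labels' protocols they were frozen in liquid nitrogen, total RNA was extracted with TRIzol, treated with DNase and enriched for poly(A) RNA with oligo(dT), and the RNA was fragmented and made into Illumina libraries. The design has 1 library per temperature, so no replicate exists and no test of temperature was possible.

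The authors deposited 1 table of normalized values with a gene ID, a definition and 1 column per library for 13485 genes. Their unit was read from the values as RPKM, since the deposited table says only that they are normalized; RPKM and FPKM cannot be told apart here. The values were never negative, the columns summed to 755678 and 689585, and the smallest steps differed from gene to gene. Among 804 genes between 0.1 and 1 RPKM in both libraries, the ratio of the 2 values lay at 1 constant times a ratio of small whole numbers for 74.8% of genes (within 0.04 on the log2 scale), against 32.3% for other constants. That constant places the depth of the 30 °C library at 1.48 times that of the 37 °C library. Gene lengths were not used here and read numbers were not recovered, so no count test was run and no counting interval is given. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. An exact 0 is reported only as listed at 0.

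Columns were matched to the libraries by their names, which repeat the sample descriptions in the labels, and 0 columns of other samples were left aside. Commas within large values were removed before they were read as numbers. A table of locus tags and RefSeq accessions was searched, and 0 of the 13485 gene IDs matched it, so gene names are the definitions in the deposited table; 5609 genes are listed there as hypothetical. Positions in the genome were not used, and neighbours are neighbours by locus number.

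Each gene was described by log2 of the 37 °C over the 30 °C value after adding a pseudocount of 1 RPKM. Genes at least 4-fold higher in either library were counted among the 6041 genes whose mean over both libraries reached 12.5 RPKM, the median mean of the 12081 genes listed above 0 in either library. Pearson and Spearman correlations were taken across genes on the log2 scale. For each gene list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins, and called outside when its percentile was below 2.5 or above 97.5. Medians of 10 genes adjacent by locus number were compared with 1000 shuffles of the gene order, with the 5th percentile of the lowest and the 95th percentile of the highest shuffled medians as limits. These percentiles and limits describe genes within the 2 libraries and say nothing of the spread between cultures.

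The lists, the comparisons, the settings and the rule for named genes were fixed before the data were examined. Lists were drawn by locus number for the toxin regions and otherwise by words in the definitions. They covered the aflatoxin cluster, the cyclopiazonic acid and kojic acid regions, polyketide and peptide synthases, cytochrome P450, MFS transporters, C6 transcription factors, heat shock and chaperones, antioxidant enzymes, glutathione S-transferases, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, the TCA cycle, glycolysis, fatty acid oxidation, sterol synthesis, the proteasome, cell wall synthesis, plant cell wall and starch hydrolases, peptidases, conidiation and development, velvet and global regulators, trehalose metabolism, iron and siderophores, housekeeping and RNA quality. Matching by words also caught some genes of other pathways, such as homocitrate synthase (AFLA_026530) and 3-isopropylmalate dehydrogenase Leu2A (AFLA_083640) in the TCA cycle list. It likewise put a vacuolar ATP synthase gene (AFLA_004560) under oxidative phosphorylation and 50S ribosomal protein L27 (AFLA_006810) under cytosolic ribosomal proteins. Another set of lists was chosen after seeing the data, by words in the definitions, and appears only in the closing observations.

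Named genes are any member of the aflatoxin list; of each other list described, up to 4 members with the largest absolute log2 ratio among those at or above 12.5 RPKM, and the most abundant member; the 12 highest and the 12 lowest log2 ratios at or above 12.5 RPKM, where genes without a function in their name may be counted only; and the 5 most abundant genes of each library. Genes of small regions and of the lists chosen later are named besides.

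The alternatives tried were pseudocounts of 0.1 and 5, no limit on expression, a limit that keeps the upper 25% of genes listed above 0, ratios centred on their median, trimmed mean scaling (trimming 30% of log ratios and 5% of levels at each end), fold limits of 2 and 8, only list members at or above 12.5 RPKM, 20 expression bins, and windows of 5 and 20 genes. After seeing the data, the dimethylallyl tryptophan synthases were left out of the synthase list and PabaA out of the conidiation list. The steps were tested on simulated data built from the deposited values with counting noise only. The read depths and gene lengths that set this noise were assumed, not taken from the data. There 100% of 200 genes altered 8-fold were recovered at the 4-fold limit, 0 of 5627 unaltered genes passed it, a list shifted by -1 on the log2 scale came out at -0.96 and percentile 0, and a simulated depth ratio of 1.5 was recovered. Noise between cultures was not simulated. Intervals in the closing observations are 95% percentile intervals from 2000 bootstrap draws of genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used.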

Results

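Mycelia of Aspergillus flavus strain NRRL3357, a filamentous fungus known for making aflatoxins, were compared after 24 h in the medium that the labels call GMS, at 30 °C and at 37 °C. Poly(A) RNA of each culture was sequenced as 1 Illumina library. With 1 library per temperature there was no replicate, so each difference reported here is between these libraries and has no replicate check. The deposited table listed RPKM values (reads scaled to gene length and library depth) for 13485 genes. Of these, 11518 were above 0 in the 30 °C library and 11157 in the 37 °C library, and 9459 and 8974 reached 1 RPKM. The RPKM values summed to 755678 at 30 °C and to 689585 at 37 °C. The number of reads is unknown, but the steps between low values placed the depth of the 30 °C library at 1.48 times that of the 37 °C library, so low values were measured less precisely at 37 °C. Ratios are given as log2 of the 37 °C over the 30 °C value after adding 1 RPKM to each, which understates the difference of genes with low values.

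At 37 °C, an O-methyltransferase gene (AFLA_077510) was listed at 785 RPKM against 1.17 at 30 °C, a log2 ratio of 8.50. An MFS multidrug transporter gene (AFLA_008410) stood at 301 against 0.07 RPKM, a fatty acid desaturase family gene (AFLA_004460) at 2417 against 13.7 RPKM, and a C4-dicarboxylate transporter/malic acid transport protein gene (AFLA_107340) at 277 against 0.65 RPKM. At 30 °C, the gene for the cell wall serine-threonine-rich galactomannoprotein Mp1 (AFLA_039410) was listed at 1465 RPKM against 0.47 at 37 °C, a log2 ratio of -9.96.

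Among the 6041 genes whose mean over both libraries was at or above 12.5 RPKM, 516 were at least 4-fold higher at 30 °C and 312 at least 4-fold higher at 37 °C. The 12 genes with the highest ratios also included those for a glyceraldehyde 3-phosphate dehydrogenase (AFLA_042390, 748 against 5.56 RPKM at 30 °C), 2 glycosyl transferases (AFLA_120930, 451 against 3.57 RPKM, and AFLA_120950, 228 against 1.80 RPKM), an arylalkylamine N-acetyltransferase (AFLA_035890, 96.2 against 0.34 RPKM) and the cytochrome P450 sterol C-22 desaturase (AFLA_028640, 103 against 0.57 RPKM), and 3 without a function in their name. The 12 with the lowest ratios included the cysteine dioxygenase gene Cdo1 (AFLA_097690, 408 RPKM at 30 °C and 0.24 at 37 °C), a muramidase gene (AFLA_119040, 747 and 1.29 RPKM), a 4-hydroxyphenylpyruvate dioxygenase gene of tyrosine breakdown (AFLA_036110, 341 and 0.56 RPKM) and a cytochrome P450 monooxygenase gene (AFLA_091000, 479 and 2.07 RPKM), and 7 without a function in their name.

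The most abundant transcript at 37 °C was that of pyruvate decarboxylase PdcA (AFLA_031570), which converts pyruvate to acetaldehyde, at 16640.0 RPKM against 1858 at 30 °C. The thiazole biosynthesis enzyme Sti35 (AFLA_037160), which makes part of thiamine, followed at 15176 against 5844 RPKM. Glyceraldehyde 3-phosphate dehydrogenase GpdA (AFLA_025100) was among the 5 most abundant genes of both libraries, at 11382 RPKM at 37 °C and 5907 at 30 °C. The translation elongation factor EF-1 alpha subunit (AFLA_090780) was among them at 30 °C, at 9212 RPKM against 7615 at 37 °C. The highest value at 30 °C, 13404 RPKM against 3619, belonged to a conserved hypothetical protein (AFLA_115930). The 10 most abundant genes held 10.1% of the RPKM sum at 30 °C and 13.4% at 37 °C.

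Across the 13485 genes the libraries had a Pearson correlation of 0.88 and a Spearman correlation of 0.88 on the log2 scale. These are correlations across genes, which are not independent replicates. Restricted to the 6041 genes at or above 12.5 RPKM, Pearson's r was 0.55. Of those genes 64.3% lay within 2-fold, and their median log2 ratio was -0.11, so that centring the ratios on this median would add 0.11 to each of them.

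**Figure D1:**
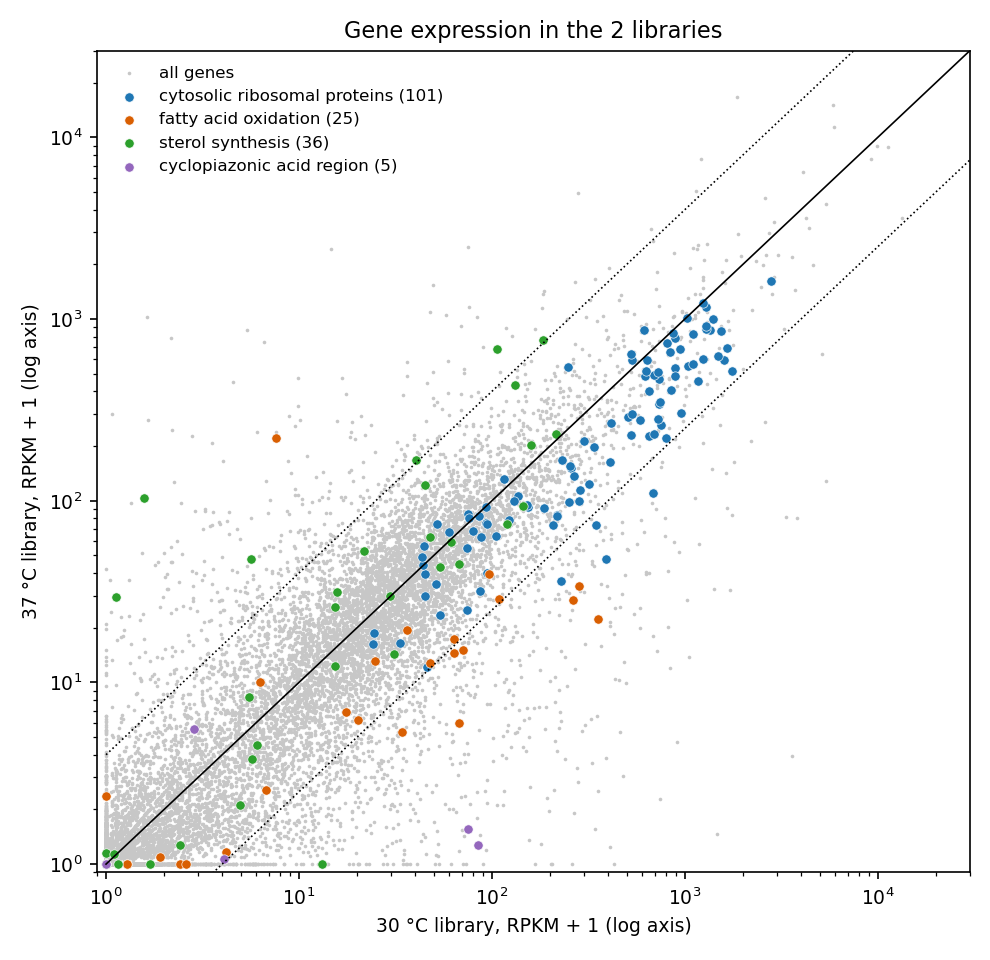
RPKM + 1 of each of the 13485 genes in the 30 °C library (horizontal, log axis) and the 37 °C library (vertical, log axis); colours mark 4 of the gene lists, the solid line equal values and the dotted lines a 4-fold difference. The 101 ribosomal protein genes lie mostly under the line of equal values (median log2 ratio -0.70), and the genes of fatty acid oxidation lie further below it (-1.40).

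Aflatoxin biosynthesis is known to depend on growth temperature in this species, and its gene cluster was examined first. Most genes of the cluster were near 0 at both temperatures, and the members with the highest values were higher at 30 °C. The co-activator AflS (AFLA_139340) was listed at 81.7 RPKM at 30 °C and 11.8 at 37 °C, and the C6 transcription activator AflR (AFLA_139360) at 31.6 and 17.8 RPKM, log2 ratios of -2.70 and -0.79. The fatty acid synthase beta subunit AflB (AFLA_139370), which acts at the start of the pathway, stood at 22.9 RPKM at 30 °C and 2.79 at 37 °C, and the integral membrane protein AflNa (AFLA_139270) at 18.6 and 1.48 RPKM. The short chain alcohol dehydrogenase AflH (AFLA_139330) had 5.59 RPKM at 30 °C and 0.59 at 37 °C.

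Other early pathway genes had similar or higher values at 37 °C. The polyketide synthase AflC (AFLA_139410), which builds the carbon skeleton, was at 0.94 RPKM at 30 °C and 4.23 at 37 °C, the norsolorinic acid reductase AflD (AFLA_139390) at 6.46 and 9.01 RPKM, and the fatty acid synthase alpha subunit aflA (AFLA_139380) at 3.03 and 3.84 RPKM. The later enzymes AflM (AFLA_139300), AflP (AFLA_139210) and AflQ (AFLA_139200) were listed at 0 in both libraries. Of the 30 loci from AFLA_139140 to AFLA_139440, 20 were below 1 RPKM in both libraries (66.7%, against 26.4% of all genes) and 10 were listed at 0 in both. At 30 °C 4 of the loci reached 12.5 RPKM, and at 37 °C 1 did.

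The list of 43 aflatoxin genes, which adds genes named for the pathway outside the interval, had a median log2 ratio of 0, at percentile 74.4 of the medians of 10000 random lists matched on expression. Of its 6 members at or above the mean of 12.5 RPKM, 2 were at least 2-fold higher at 30 °C and 1 at 37 °C. The latter was the developmental regulator VeA (AFLA_066460), at 30.3 RPKM at 30 °C and 99.5 at 37 °C. At values below 1 RPKM the ratio of a gene rests on few reads, and whether differences among those genes could be detected at this depth was not tested.

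Beside the aflatoxin genes lies the region for cyclopiazonic acid, another mycotoxin, and its genes stood apart more clearly. The dimethylallyl tryptophan synthase DmaT (AFLA_139480) was listed at 83.6 RPKM at 30 °C and 0.28 at 37 °C, and the FAD dependent oxidoreductase MaoA (AFLA_139470) at 74.1 and 0.56 RPKM. The hybrid PKS/NRPS enzyme of the pathway (AFLA_139490) had 3.11 RPKM at 30 °C and 0.07 at 37 °C, whereas the MFS cyclopiazonic acid transporter (AFLA_139460) had 1.86 and 4.54 RPKM. The median log2 ratio of the 5 loci was -1.94, at percentile 0.105 of random lists.

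**Figure D2:**
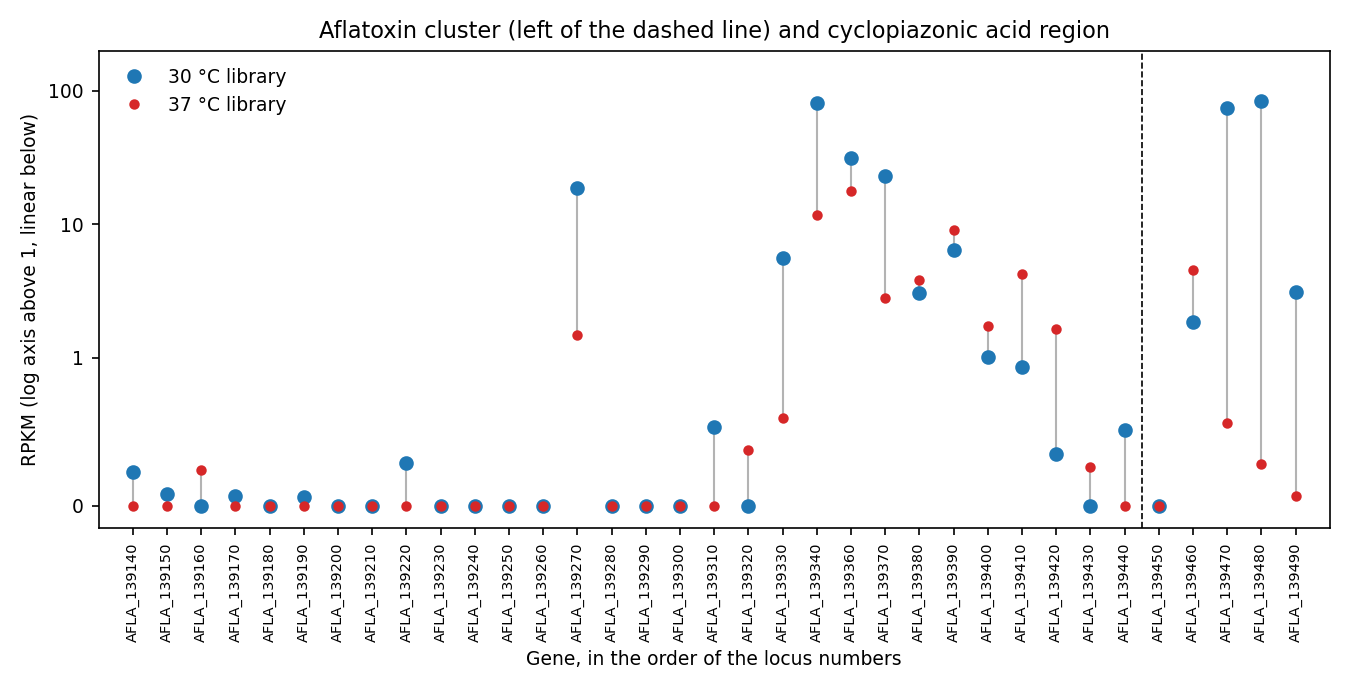
RPKM in the 30 °C library (blue) and the 37 °C library (red) of the 30 loci of the aflatoxin interval and the 5 loci of the cyclopiazonic acid region, in the order of their locus numbers; the vertical axis is logarithmic above 1 RPKM and linear below, and a grey line joins the values of a gene. AflS (AFLA_139340) is the highest of the aflatoxin loci, at 81.7 RPKM at 30 °C, and 10 loci of the interval are at 0 in both libraries.

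Of the 28 gene lists, 10 had a median outside the middle 95% of their random lists, and centring the ratios changed the sign of none of these 10. For lists of genes drawn at random, 1.4 would be outside. Genes of a list can vary together and some lists share members, so 10 against 1.4 does not test an effect of temperature. Genes for making ribosomes and for oxidising fatty acids were lower at 37 °C. The list matched to cytosolic ribosomal proteins also took in 50S ribosomal protein L27 (AFLA_006810, 85.1 RPKM at 30 °C and 81.9 at 37 °C), not a 40S or 60S protein. All 101 genes matched were at or above 12.5 RPKM, and 36 of them were at least 2-fold higher at 30 °C against 1 at 37 °C. Their median log2 ratio of -0.70 was below that of all 10000 random lists (percentile 0). The ratio was lowest for 40S ribosomal protein S21 (AFLA_092120, 389 RPKM at 30 °C and 47.1 at 37 °C), 60S ribosomal protein L37a (AFLA_002560, 228 and 35.4 RPKM) and 40S ribosomal protein S25 (AFLA_083050, 683 and 109.9 RPKM). The most abundant, 40S ribosomal protein S3Ae (AFLA_047870), was at 2787 and 1619 RPKM. The difference was greater in the proteins with higher numbers, which tend to be smaller (median log2 ratio -1.02, against -0.47 for those with lower numbers). The 72 genes of ribosome biogenesis had a median of -0.83, also at percentile 0. Of the 62 at or above 12.5 RPKM, 21 were at least 2-fold higher at 30 °C and 1 at 37 °C. Among them the pre-rRNA-processing protein esf2 (AFLA_002730) had 32.4 RPKM at 30 °C and 8.57 at 37 °C, and a nucleolar GTPase (AFLA_110550) 71.7 and 21.1 RPKM.

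The 25 genes of fatty acid oxidation had a median log2 ratio of -1.40, at percentile 0. Of the 14 at or above 12.5 RPKM, 11 were at least 2-fold higher at 30 °C, among them 3 acyl-CoA dehydrogenase genes (AFLA_084820, 356 RPKM at 30 °C and 21.2 at 37 °C; AFLA_014310, 66.4 and 4.96 RPKM; AFLA_049020, 263 and 27.4 RPKM). The single member at least 2-fold higher at 37 °C was a 3-hydroxyacyl-CoA dehydrogenase gene (AFLA_007970), at 6.59 and 221 RPKM.

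Antioxidant enzymes and peptidases were also lower at 37 °C as lists. The 36 antioxidant genes had a median of -0.60 (percentile 0.44). Of the 25 at or above 12.5 RPKM, 3 were at least 2-fold higher at 37 °C and 11 at 30 °C. These included 2 catalase genes (AFLA_096210, 105.8 RPKM at 30 °C and 1.11 at 37 °C; AFLA_034380, 66.0 and 2.10 RPKM) and a thioredoxin gene (AFLA_083120, 720.5 and 13.9 RPKM). The superoxide dismutase SOD1 (AFLA_099000), the most abundant of the list, was at 831 and 472 RPKM. The 134 peptidase genes had a median of -0.42 (percentile 0.03). Of the 87 at or above 12.5 RPKM, 28 were at least 2-fold higher at 30 °C and 8 at 37 °C. A glutamate carboxypeptidase gene (AFLA_103940) was at 2192 and 214 RPKM, a zinc metalloproteinase gene (AFLA_019680) at 434 and 24.8 RPKM, and the secreted dipeptidyl peptidase DppV (AFLA_045980) at 121 and 8.12 RPKM.

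Glycolytic and cell wall genes were higher at 37 °C as lists. The 31 genes matched to glycolysis had a median log2 ratio of 0.13 (percentile 99.1). They include genes caught by name only, such as a glucokinase regulator family gene (AFLA_005010), listed at 0 in both libraries. Of the 20 at or above 12.5 RPKM, 8 were at least 2-fold higher at 37 °C and 1 at 30 °C. The 6-phosphofructokinase alpha subunit (AFLA_024480), which catalyses a committed step of the pathway, had 51.2 RPKM at 30 °C and 211 at 37 °C, and a phosphoglycerate mutase family gene (AFLA_091380) 38.5 and 219 RPKM. The exception was a fructose-bisphosphate aldolase gene (AFLA_119950), at 23.5 and 2.01 RPKM. The 82 genes of the cell wall had a median of 0.18 (percentile 99.9). Of the 52 at or above 12.5 RPKM, 19 were at least 2-fold higher at 37 °C and 7 at 30 °C. Of these, the alpha-1,3-glucan synthase Ags1 (AFLA_023460) had 0.80 RPKM at 30 °C and 43.3 at 37 °C, whereas the class V chitinase Chi100 (AFLA_054470), with 33.6 and 0.05 RPKM, an antigenic cell wall galactomannoprotein gene (AFLA_040040), with 31.0 and 0.34 RPKM, and Mp1 were among the members higher at 30 °C.

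The 35 genes for iron and siderophores had a median log2 ratio of 0.10, at percentile 97.6. Their median RPKM went the other way, at 1.41 at 30 °C and 0.36 at 37 °C. Of the 9 at or above 12.5 RPKM, 4 were at least 2-fold higher at 37 °C and 0 at 30 °C. These 4 were a low affinity iron transporter gene (AFLA_040230, 1.5 RPKM at 30 °C and 25.2 at 37 °C), the siderophore transcription factor SreA (AFLA_132440, 47.0 and 178 RPKM), a ferric-chelate reductase gene (AFLA_031830, 39.0 and 106 RPKM) and a siderophore biosynthesis protein gene (AFLA_029140, 88.2 and 200.1 RPKM). This list lay inside the range of its random lists with a pseudocount of 5 (percentile 96.3), with trimmed mean scaling (96.1), over the members at or above 12.5 RPKM alone (96.8) and with 20 expression bins (97.3).

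The list of polyketide and peptide synthases, the core enzymes of many secondary metabolites, also took in 7 dimethylallyl tryptophan synthase genes, which are prenyltransferases. Its genes were mostly near 0, with a median RPKM of 0.205 at 30 °C and 0.195 at 37 °C over the 86 members. Their median log2 ratio of 0.03 was at percentile 99.8, but their mean was -0.04, and the median of the 8 members at or above 12.5 RPKM was -2.89, at percentile 0. Without the prenyltransferases, left out after seeing the data, 6 members remained at or above that level, 3 at least 2-fold higher at 30 °C and 3 at 37 °C, with a median of -0.22 (percentile 42.4). Of the 8, 5 were at least 4-fold higher at 30 °C and 2 at 37 °C. The nonribosomal peptide synthase Pes1 (AFLA_069330) had 151 RPKM at 30 °C and 6.2 at 37 °C, and the prenyltransferases DmaT and AFLA_060680, the latter at 31.2 and 1.46 RPKM, were also higher at 30 °C. Another nonribosomal peptide synthase gene (AFLA_004450) was at 0.05 and 35.5 RPKM.

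**Figure D3:**
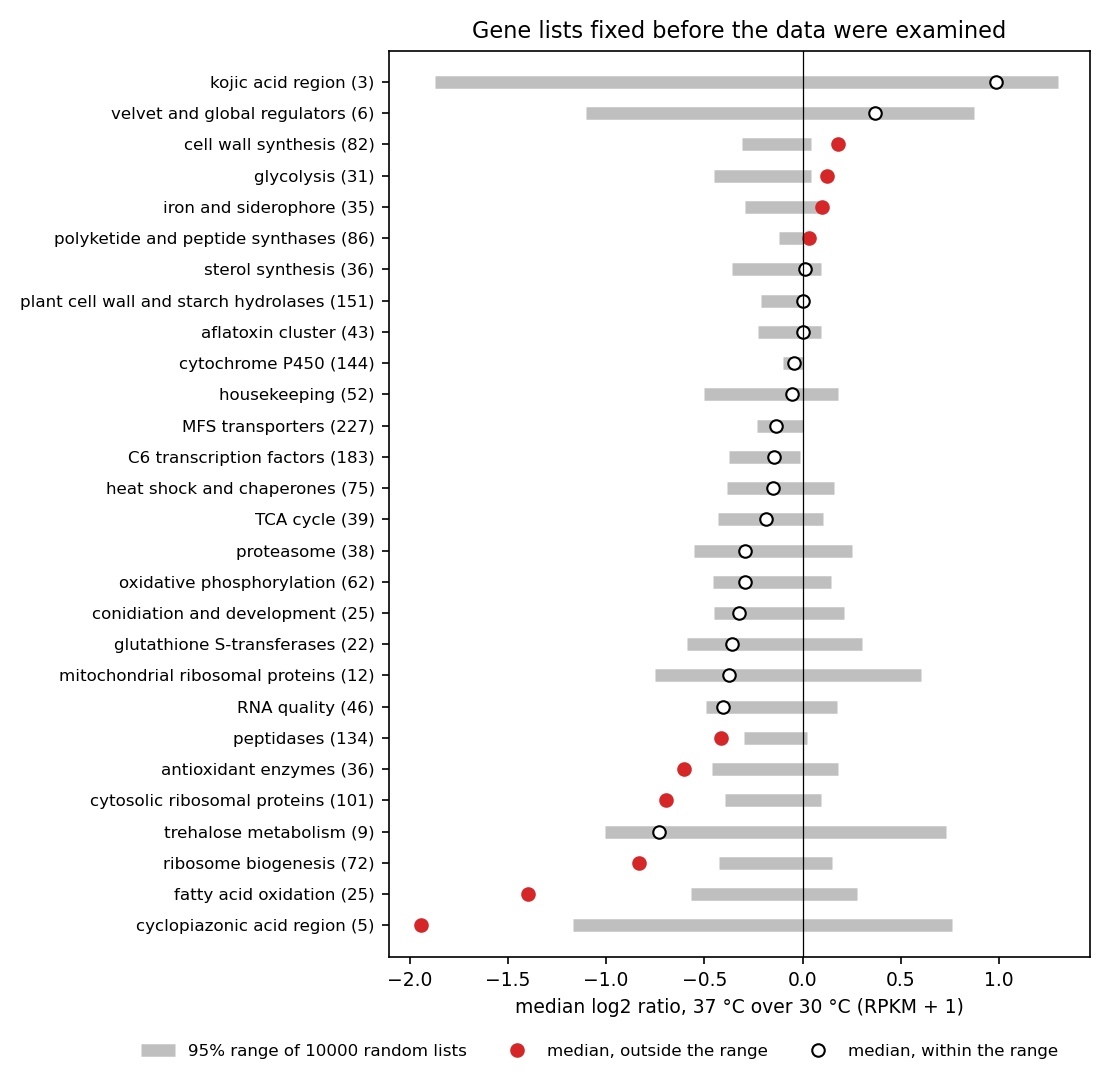
Median log2 ratio (37 °C over 30 °C, RPKM + 1) of the 28 gene lists, with the number of members in brackets; grey bars span the middle 95% of the medians of 10000 random lists of the same size matched on expression, and red points lie outside them. Cyclopiazonic acid genes (-1.94) and fatty acid oxidation (-1.40) lie furthest to the left, and the 10 red points hold 6 lists with a negative and 4 with a positive median.

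Heat shock and chaperone genes were not higher at 37 °C as a list. The 75 members had a median log2 ratio of -0.15, at percentile 38.2, and of the 69 at or above 12.5 RPKM 13 were at least 2-fold higher at 30 °C and 2 at 37 °C. The chaperone/heat shock protein Hsp12 (AFLA_052860) had 3811 RPKM at 30 °C and 79.6 at 37 °C, a heat shock protein Hsp30-like gene (AFLA_037820) 814 and 19.3 RPKM, and the heat shock protein/chaperonin HSP78 (AFLA_068370) 259 and 38.7 RPKM. The most abundant member, heat shock protein Hsp30/Hsp42 (AFLA_060260), was at 3053 and 2258 RPKM.

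Sterol synthesis had several members higher at 37 °C. Over the 36 genes the median was 0.01 (percentile 91.4), but over the 22 at or above 12.5 RPKM it was 0.59 (percentile 99.5), with 10 at least 2-fold higher at 37 °C and 1 at 30 °C. Besides the C-22 desaturase, the squalene monooxygenase Erg1 (AFLA_061500) had 105.1 RPKM at 30 °C and 687 at 37 °C, and 3 HMG-CoA reductase genes, for the enzyme that limits the rate of sterol synthesis, had 0.12 and 28.7 RPKM (AFLA_009170), 4.66 and 46.5 RPKM (AFLA_126760) and 20.7 and 52.1 RPKM (AFLA_092010). Another HMG-CoA reductase gene (AFLA_061070), below the limit, went the other way, at 12.1 RPKM at 30 °C and listed at 0 at 37 °C. The most abundant member, 14-alpha sterol demethylase Cyp51A (AFLA_036130), was at 184 and 764 RPKM.

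The conidiation and development list had a median of -0.32 (percentile 10.3) over 25 genes and of -1.09 (percentile 0.80) over the 11 at or above 12.5 RPKM, of which 6 were at least 2-fold higher at 30 °C and 2 at 37 °C. The former included the conidiation proteins Con-6 (AFLA_044800, 146 RPKM at 30 °C and 5.22 at 37 °C) and Con-10 (AFLA_083110, 117 and 6.25 RPKM) and the spore-specific catalase CatA (AFLA_056170, 229 and 72.8 RPKM). The list also caught para-aminobenzoate synthase PabaA (AFLA_055160, 76.0 and 35.2 RPKM), an enzyme of folate synthesis, by its name. The latter were VeA (AFLA_066460, 30.3 and 99.5 RPKM) and the conidiation transcription factor FlbC (AFLA_137320, 23.1 and 52.2 RPKM). The 6 velvet and global regulator genes had a median of 0.37 (percentile 83.8). In this list a LaeA-like methyltransferase gene (AFLA_035950) had 15.7 RPKM at 30 °C and 474.5 at 37 °C, another (AFLA_121330) had 72.1 and 19.5 RPKM, and the regulator of secondary metabolism LaeA itself (AFLA_033290) had 68.6 and 44.6 RPKM.

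The transporter, detoxification and regulator families had medians inside their ranges. The 144 cytochrome P450 genes had a median of -0.05 (percentile 14.5), which changes sign when the ratios are centred. Over the 25 of them at or above 12.5 RPKM it was -0.68 (percentile 1.17), where a benzoate 4-monooxygenase cytochrome P450 gene (AFLA_097470) had 178 RPKM at 30 °C and 0.29 at 37 °C. The 227 MFS transporter genes had a median of -0.14 (percentile 24.8), with values both ways. Among these, an MFS monosaccharide transporter gene (AFLA_134420) had 73.9 RPKM at 30 °C and 2499 at 37 °C, and an MFS peptide transporter gene (AFLA_122370) had 66.6 and 0.18 RPKM. The 183 C6 transcription factor genes were at -0.15 (percentile 69.2) and the 22 glutathione S-transferase genes at -0.36 (percentile 15.6).

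Energy metabolism and the proteasome also lay inside their ranges. The 62 genes matched to oxidative phosphorylation, which include vacuolar ATP synthase genes such as AFLA_004560, had a median log2 ratio of -0.30 (percentile 16.5). Medians were -0.19 for the 39 genes matched to the TCA cycle (24.0) and -0.37 for the 12 mitochondrial ribosomal proteins (18.8). The 38 proteasome genes were at -0.29 (23.9) and the 9 genes of trehalose metabolism at -0.73 (8.13). The TCA cycle list held 2 genes defined as citrate synthase Cit1, 1 at 632 RPKM at 30 °C and 39.3 at 37 °C (AFLA_049290) and the other at 666 and 588 RPKM (AFLA_007020), and aconitate hydratase (AFLA_127840), at 10.3 and 69.4 RPKM. Its lowest ratio was that of succinyl-CoA:3-ketoacid-coenzyme A transferase ScoT (AFLA_052610, 833 and 10.9 RPKM), an enzyme of ketone body use and not of the cycle.

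The 151 hydrolases of plant cell walls and starch had a median of 0 (percentile 88.8). In this list an extracellular endo-polygalacturonase gene (AFLA_105920) was at 2.53 RPKM at 30 °C and 207 at 37 °C. The 3 loci of the kojic acid region (AFLA_096040, AFLA_096050 and AFLA_096060) had a median of 0.98 (percentile 94.8) with a highest value of 8.87 RPKM, that of the protein RDR1 gene (AFLA_096050) at 30 °C. The 52 housekeeping genes had a median of -0.05 (percentile 72.8), which changes sign when the ratios are centred, and histone H3 (AFLA_017610) was at 2532 RPKM at 30 °C and 1979 at 37 °C. The list meant for RNA quality matched 46 genes of tRNA and rRNA metabolism (median -0.41, percentile 6.84), which are protein genes and do not measure RNA quality. Its median over the 30 members at or above 12.5 RPKM was -0.63 (percentile 1.08).

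Genes that differed in the same direction also lay side by side. In windows of 10 genes adjacent by locus number, 6 regions were higher at 30 °C and 5 at 37 °C past the limits set by 1000 shuffles of the gene order, median log2 ratios of -2.28 and 1.57. The region with the lowest window median, -3.19, ran from AFLA_099130 to AFLA_099300 and held the genes for both subunits of 3-methylcrotonyl-CoA carboxylase, MccA (AFLA_099250, 131 RPKM at 30 °C and 4.25 at 37 °C) and MccB (AFLA_099280, 119 and 4.42 RPKM), and isovaleryl-CoA dehydrogenase IvdA (AFLA_099270, 144 and 3.43 RPKM), which break down leucine. The region from AFLA_036010 to AFLA_036150 held the tyrosine breakdown genes homogentisate 1,2-dioxygenase HmgA (AFLA_036090, 131 and 19.3 RPKM) and fumarylacetoacetate hydrolase FahA (AFLA_036080, 103 and 17.9 RPKM). It overlapped a region higher at 37 °C from AFLA_036010 to AFLA_036040, and also held genes higher at 37 °C, an NADH-dependent flavin oxidoreductase gene (AFLA_036010, 26.8 and 120.7 RPKM) and Cyp51A (AFLA_036130, 184 and 764 RPKM). The region from AFLA_060620 to AFLA_060750 held the dimethylallyl tryptophan synthase gene AFLA_060680 beside a phenylalanine ammonia-lyase gene (AFLA_060700, 29.2 and 3.72 RPKM) and a toxin biosynthesis protein gene (AFLA_060710, 139.5 and 31.4 RPKM). The other 3 began at AFLA_077210, AFLA_061020 and AFLA_124940.

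At 37 °C the highest window median, 2.96, lay between AFLA_120860 and AFLA_121030, with both glycosyl transferase genes named among the highest ratios and the glycan biosynthesis protein PigL (AFLA_120940, 9.98 RPKM at 30 °C and 176 at 37 °C). The region from AFLA_035880 to AFLA_036040 held the LaeA-like methyltransferase gene AFLA_035950 and the arylalkylamine N-acetyltransferase gene AFLA_035890. The region from AFLA_077430 to AFLA_077540 held the O-methyltransferase gene AFLA_077510 and a cinnamoyl-CoA reductase gene (AFLA_077450, 23.9 and 184 RPKM). The remaining 2 began at AFLA_136330 and AFLA_075840. Genes within these regions were named after their values were seen. With windows of 5 genes, 3 regions passed at 30 °C and 2 at 37 °C, and at 37 °C 2 passed with windows of 20 genes and 3 with a pseudocount of 5.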

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

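No paired analysis was possible because there is 1 library per temperature, and for the same reason no library could be left out. Raw counts scaled to the library total were not run, since the table holds no counts. Of 196 results under the alternatives, 172 stayed within 1.5 times the count, within the bootstrap interval of the correlation or on the same side of the random lists. Centring shifts a list and its random lists alike, so it cannot move a list's percentile, and its unchanged percentiles are no check. The 172 include the centred results of all 28 lists, which could not have come out otherwise. More genes were at least 4-fold higher at 30 °C than at 37 °C under each alternative. With no limit on expression 845 genes were so at 30 °C, with the upper 25% of genes 168 were at 37 °C and 285 at 30 °C, with a fold limit of 2 the counts were 929 and 1226, and with a fold limit of 8 they were 126 and 285, as fewer or more genes or a lower or higher bar would give. Centring took the share of these genes higher at 37 °C from 37.7% to 41.8%, and trimmed mean scaling to 41.6%. Of the 10 lists outside their random range, 8 were outside it on the same side under each alternative. Over members above the expression limit alone, the median of polyketide and peptide synthases reversed to -2.89, as most members lie near 0, and medians moved outside the range for cytochrome P450 (-0.68), sterol synthesis (0.59), conidiation and development (-1.09) and the RNA quality list (-0.63). Leaving out the dimethylallyl tryptophan synthases, a choice made after seeing the data, brought the median of the synthases above the limit to -0.22, inside the range. Leaving out PabaA brought that of conidiation above the limit to -1.26, but that of the whole conidiation list to -0.16 (percentile 33.2). The iron and siderophore list lay inside it with a pseudocount of 5 (0.022), trimmed mean scaling (0.12), members above the limit alone (0.65) and 20 expression bins (0.10); the cause was not tested. Pearson's r was 0.86 with a pseudocount of 5 and 0.55 over genes above the limit. Windows of 5 genes gave 3 regions higher at 30 °C and 2 at 37 °C, windows of 20 genes gave 2 at 37 °C, and a pseudocount of 5 gave 3 at 37 °C; the cause was not tested. Depth limits genes below 1 RPKM, whose values rest on few reads, more so at 37 °C.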

Other observations

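The lists described here were chosen after seeing the data, as were the tests of scaling, gene length and the aflatoxin genes; the tests on gluconeogenic genes and on conidiation genes were set before their values were seen. Medians and counts of the lists chosen that way only describe their members, and their percentiles among random lists are left out because the choice would decide them. All 6 genes for breaking down branched-chain amino acids were at least 4-fold higher at 30 °C (median log2 ratio -5.38), among them a 2-oxoisovalerate dehydrogenase complex alpha subunit gene (AFLA_128600, 329.5 RPKM at 30 °C and 2.62 at 37 °C). The 4 genes matched to the glyoxylate cycle, which makes organic acids from acetyl units, had a median of -4.45. Before that, 2 isopropylmalate synthase genes of leucine synthesis (AFLA_084660 and AFLA_089720), first matched by name, were taken out once values had been seen. Isocitrate lyase AcuD (AFLA_052400) was at 1049.8 and 12.9 RPKM and malate synthase AcuE (AFLA_049390) at 1718 and 31.4 RPKM. The 17 genes of tyrosine breakdown had a median of -0.62, and of the 6 above the expression limit 5 were at least 2-fold higher at 30 °C. The 60 amino acid transporter genes had a median of -0.16, and the amino acid permease Dip5 (AFLA_046230) was at 265 and 0.90 RPKM.

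Genes of nitrate and ammonium use and of sulfate assimilation included several that were higher at 37 °C. Nitrate reductase NiaD (AFLA_018810) had 5.06 RPKM at 30 °C and 239 at 37 °C, nitrite reductase NiiA (AFLA_018800) 9.17 and 277 RPKM, and the ammonium transporter MeaA (AFLA_130040) 2.20 and 69.4 RPKM; these were the 3 of the 8 genes of the list above the expression limit, and the list had a median log2 ratio of 2.21. The 9 genes of sulfate assimilation had a median of 1.08, where of the 8 above the limit 5 were at least 2-fold higher at 37 °C and 3 lay within 2-fold, with the phosphosulfate reductase Met16 (AFLA_100690) at 6.58 and 237 RPKM. The 3 alpha-1,3-glucan synthase genes, which make a cell wall polymer, had a median of 3.60, and Ags3 (AFLA_116810) was at 8.51 and 114 RPKM. The 14 autophagy genes had a median of -0.10.

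Fatty acid oxidation genes, from a list fixed before the data were examined, were higher at 30 °C (median log2 ratio -1.40), and the glyoxylate and branched-chain amino acid genes were added to them for being so, which makes 35 catabolic genes whose joint size restates that choice. Scaling of the libraries does not account for the pattern, since centring left the fixed list at -1.29 and the joined set at -1.79. Conidia in the 30 °C culture stay open. At 30 °C 0 of 7 conidiation regulators and hydrophobins reached 12.5 RPKM, which met the bound set against conidia. WetA (AFLA_052030) was the highest at 6.52, and the median log2 ratio of the 7 was 0.21 (percentile 95.3). Con-6 (AFLA_044800, 146 RPKM at 30 °C and 5.22 at 37 °C), Con-10 (AFLA_083110, 117 and 6.25 RPKM) and the spore-specific catalase CatA (AFLA_056170, 229 and 72.8 RPKM) go with conidia. So does the conidiation list over members above the limit (-1.09, percentile 0.80, and -1.26 without PabaA). The whole conidiation list lay inside its range (-0.32, percentile 10.3, and -0.16, percentile 33.2, without PabaA). The bound was set on the 7 genes alone. The other conidiation genes and lists were weighed against it only after their values were seen. Another candidate explanation is that the carbon source was exhausted in the 30 °C culture at 24 h, for which phosphoenolpyruvate carboxykinase AcuF (AFLA_036370, 1804 RPKM at 30 °C and 162 at 37 °C) and fructose-1,6-bisphosphatase Fbp1 (AFLA_027310, 786 and 79.2 RPKM) should be higher at 30 °C, and their median was -3.38, which as a list lay inside the range of random pairs (percentile 3.13). This rests on 2 genes and 1 culture each. The prediction was written after the glyoxylate cycle genes were seen to be higher at 30 °C. Its result cannot tell exhaustion from a direct effect of temperature on these genes, which stays open. Ribosomal protein (-0.70) and ribosome biogenesis genes (-0.83) were also higher at 30 °C as lists, and the autophagy genes had a median of -0.10. Exhaustion of the carbon source was not tested against these lists.

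Ribosomal protein genes were lower at 37 °C, and scaling of the libraries does not account for it, as the list's median was -0.59 after centring (-0.74 to -0.44). A loss of short transcripts from the 37 °C library could contribute. Across the 92 genes with a numbered name, higher numbers, which tend to mark smaller proteins, went with lower ratios (Spearman's rho -0.49, -0.64 to -0.31), and the 47 with lower numbers had a median of -0.47 (-0.66 to -0.24), too close to both predictions to decide. The number is a rough stand-in for length, the genes matched include 50S ribosomal protein L27 (AFLA_006810), and gene lengths were not used here. Ribosome biogenesis genes were also lower at 37 °C (-0.83), while mitochondrial ribosomal proteins lay inside their range (-0.37, percentile 18.8). Without gene lengths these lists do not decide the question. Gene length bias, an effect of temperature and another difference between the cultures therefore cannot be told apart.

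Most aflatoxin genes were near 0 at 30 °C as well as at 37 °C. Reads lost over the whole locus would have left no gene of the interval above the expression limit, yet 4 reached it at 30 °C. Unexpressed pathway regulators would have placed AflR (AFLA_139360) in the lower part of the genes listed above 0, but it was at percentile 68.4 at 30 °C, and the co-activator AflS (AFLA_139340) was at percentile 86.4. At 37 °C AflR and AflS were at percentiles 57.2 and 49.3, and 1 gene of the interval reached the limit. Both explanations were examined in the 30 °C library only, and neither is excluded for the 37 °C library. The bounds for both explanations were set after the values were seen. Beyond the transcripts of these regulators, no biological explanation was tested.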
